A study of Mus musculus with 12 samples.

How the data were processed

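Total RNA and ribosome-protected fragments (RPF) were measured in CD4+ T cells of mouse lymph nodes, isolated by depleting other cells with beads. Per the labels, total RNA libraries came from a small part of the cells, with polyadenylated RNA taken up on beads. The remaining cells were pooled 2 by 2 and treated with cycloheximide and micrococcal nuclease before RPF libraries were made from the fragments. The groups were WT and Anaef total RNA with 4 libraries each and WT and Anaef RPF with 2 pools each, taken from the labels. The labels do not say which animals went into which pool, so p-values measure only the spread between these samples.

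The deposited values were raw read counts per gene for total RNA and raw counts after masking for RPF, with no normalization by the authors. The submitters' processing notes name TopHat 1.4.1 and the build GRCm38. The counting tool, its annotation and strand setting, and what was masked are not given in the sources used here. The table held 45669 genes or joined genes, of which 44595 were matched to GENCODE annotation of GRCm38, 263 joined several identifiers and 811 had no match. Of 6486 protein-coding genes with at least 10 CPM in total RNA, 87 had 0 RPF counts and 194 had under 10 over the 4 RPF libraries. Some genes share reads with copies. mt-Co2 and its pseudogene Gm28661 had 1645789 and 1645352 counts in WT replicate 1, so pseudogene and mitochondrial counts overlap.

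Depth was 15326842 to 40046317 counts per library in WT total RNA, 18580747 to 39467754 in Anaef total RNA, 4044330 to 7009342 in WT RPF and 2868943 to 3464868 in Anaef RPF. Counting intervals at 95% and floors of 3 counts over the group cover counting error only, since reads without molecular identifiers are not independent molecules. The fold of a gene with no counts in a group is a lower bound against that floor.

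Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment at 0.05. Total RNA was fitted on its 8 libraries and RPF on its 4. Translational efficiency was the interaction of genotype and assay over the 12 libraries, and the WT ratio of RPF to total RNA used the 6 WT libraries. Standard errors were derived from the F statistic and the fold change. Values per library were CPM on the TMM-scaled library size, and log2 CPM used a prior count of 2. CPM of the interaction fit are on the scale of all 12 libraries and differ from those of the separate fits.

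Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members, with an estimated correlation and fry beside it. Adjusted p given for lists are those of camera unless said otherwise. The 30 lists covered translation (cytosolic ribosomal proteins, translation factors of the TOP class, mitochondrial ribosomal proteins), metabolism (nuclear oxidative phosphorylation, mitochondrially encoded genes, glycolysis, sterol synthesis and uptake, ATF4 and amino acid response), spliceosome components and proteasome subunits. For signalling and stress they were mTORC1 components, Ras-ERK components, immediate early and tonic TCR-responsive genes, interferon-stimulated genes and heat shock. For T cells they were naive, activated and memory, follicular and peripheral helper, anergy and chronic stimulation, regulatory, Th1, Th2 and Th17, cell cycle and CD4 identity lists. For other cell types they were B cell, plasma cell, CD8 T cell, NK and gamma-delta T cell, myeloid and dendritic, stromal and endothelial, and erythroid lists. Some members stand in more than 1 list; the helper list shares Pdcd1, Tox, Tigit and Izumo1r with the anergy list, and the plasma cell list holds Prdm1 and Irf4, which activated T cells also express. A list mean per library was compared by an exact permutation test over all assignments of the libraries.

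The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. By that rule Rasgrp1 was always named. A genotype comparison with at least 10 called genes would name the 10 largest rises and falls, which none reached, and one with fewer names all called genes and the 5 with the smallest p in each direction as not passing. For lists, up to 4 members with the smallest p were named, and for other cell types the 2 most abundant members. Some members that this rule names are not reported here.

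Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a mean of at least 50 counts, limma-voom, leaving out mitochondrial, Ig and TCR genes, a fit on all 12 libraries, quality weights for the interaction, 1 surrogate variable from sva 3.50.0 for total RNA, and leaving out each library in turn. Chosen after seeing the data were fits on nuclear protein-coding genes only, RLE size factors for the lists, removal of a trend with coding length or GC content from each library (lowess, span 0.3), and the correlation of the assays without lists of other cell types and Ig and TCR segments. RLE moved the median of all genes by 0.0072, -7e-04 and 0.0351 on the log2 scale in total RNA, RPF and the interaction. Unmasked RPF columns were not used here.

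The pipeline was tested on simulated data with known changes. In total RNA it recovered 4.2%, 26.5%, 63.3% and 95.6% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 4 false calls among 95. In RPF it recovered 8%, 40.8%, 98% and 98%, with 11 false calls among 134. For the interaction it recovered 0%, 2%, 6% and 28%, with 1 false call among 19. A list shifted by 0.5 was called in each, with adjusted p of 4.33e-17, 1.17e-17 and 1.67e-09 at the preset correlation and 0.000717, 0.916 and 0.0389 with an estimated one. No other list was called, 0 of 28, 0 of 27 and 0 of 29. The simulated genes were drawn independently, with the spread fitted for genes of their abundance. The simulation therefore holds no extra spread of single genes and no correlation between genes. Recovery in the real data may be lower, and the absence of other list calls does not carry over to correlated genes.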

Results

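The data were read counts per gene from CD4+ T cells of the lymph nodes of 12-week-old C57BL6 mice, either wild type (WT) or homozygous for Anaef, a point-mutant allele of Rasgrp1. Rasgrp1 encodes the exchange factor that loads Ras with GTP below the T cell receptor (TCR). Total RNA was sequenced from 4 WT libraries (replicates 1 to 4) and 4 Anaef libraries (replicates 5 to 8). Ribosome-protected fragments (RPF), the short stretches of mRNA that a ribosome shields from nuclease, were sequenced from 2 WT pools (1B and 2B) and 2 Anaef pools (3B and 4B), each made from 2 samples. The total RNA libraries held 35083582, 40046317, 15326842 and 22686730 counts in WT replicates 1 to 4. They held 18580747, 33537273, 38449462 and 39467754 in Anaef replicates 5 to 8. The RPF libraries were shallower, with 7009342 and 4044330 counts in WT 1B and 2B and 3464868 and 2868943 in Anaef 3B and 4B. Values below are CPM, the read counts divided by the scaled library size and put on a common total, as mean ± SD over the libraries of a group, and log2 fold changes of Anaef over WT with their standard error (SE). Coordinates are those of GRCm38.

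Mitochondrially encoded transcripts took 16.4% to 27.8% of the total RNA counts in WT and 17.0% to 25.01% in Anaef, and under 1% in each RPF library. WT replicate 3, the shallowest total RNA library, had 27.8% mitochondrial and 28.2% pseudogene counts, and it stood apart on the second principal component of total RNA. Anaef replicate 6 stood apart on the other of the leading pair of components, which carried 23.3% and 21.6% of the variance. In RPF the first component carried 50.7%, at 27.7 and 14.1 in WT 1B and 2B and -4.65 and -37.1 in Anaef 3B and 4B. Immunoglobulin (Ig) genes, which B cells and plasma cells transcribe, took 0.876%, 1.87%, 0.354% and 0.378% of the counts in WT total RNA and 0.283%, 0.194%, 0.172% and 0.192% in Anaef. Their share in the RPF libraries was 8.09% and 3.17% in WT and 2.54% and 0.790% in Anaef.

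Rasgrp1 (ENSMUSG00000027347, chromosome 2, 117279993 to 117343001) was read from every library. Its total RNA level was 503 ± 72.1 CPM in WT (n = 4) and 582 ± 92.9 CPM in Anaef (n = 4), a log2 fold change of 0.21 with an SE of 0.16 and an adjusted p of 0.945. WT replicate 3 gave 610 CPM, and the other WT libraries 453 to 479 CPM. In RPF it was 161 ± 16.4 CPM in WT (n = 2) and 114 ± 13.6 CPM in Anaef (n = 2), a log2 fold change of -0.50 with an SE of 0.16 and an adjusted p of 0.363. The change in its RPF relative to its total RNA was -0.72 with an SE of 0.27 and an adjusted p of 1. Anaef alters the protein, so the level of the transcript is no check of which libraries carried the allele.

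The total RNA comparison addresses which transcripts differ between Anaef and WT CD4+ T cells. Transcripts of antibody-secreting cells were the clearest difference. Igha (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236), the constant region of IgA, fell from 300.5 ± 54.9 CPM in WT to 76.2 ± 21.3 CPM in Anaef (n = 4 each), a log2 fold change of -1.98 (SE 0.22, adjusted p = 0.0268). The other genes that passed were variable segments of the Ig kappa light chain, which make up the antigen-binding part of an antibody. Of the 4 genes that passed out of 17876 tested, all were Ig genes, and each was lower in all 4 Anaef libraries than in any WT library.

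Igkv4-72 (ENSMUSG00000076545, chromosome 6, 69226854 to 69227433) fell from 28.2 ± 17.7 to 0.555 ± 0.455 CPM, a log2 fold change of -5.62 (SE 0.65, adjusted p = 0.0268). Igkv6-17 (ENSMUSG00000095794, chromosome 6, 70371439 to 70371993) fell from 42.0 ± 23.4 to 0.698 ± 0.632 CPM, a log2 fold change of -5.84 (SE 0.74, adjusted p = 0.0436). Igkv5-48 (ENSMUSG00000076563, chromosome 6, 69726573 to 69727138) had 2402 counts over the WT libraries and 2 over the Anaef libraries, a ratio of 1380.3 with a 95% counting interval of 382 to 11404 (adjusted p = 0.0268). Ig segments resemble one another closely and reads may be shared between them, so the identity of single segments is uncertain. Of the 163 Ig segments tested, 113 were lower in Anaef and 1 was higher at an unadjusted p under 0.05. With 1 surrogate variable 1 gene passed, with limma-voom 2 passed, and without Anaef replicate 5, 7 or 8 none did (0 in each), while DESeq2 called 166. Without WT replicate 1, 2, 3 or 4 the counts were 2, 1, 3 and 2, without Anaef replicate 6 it was 2, and 1004 genes had an unadjusted p under 0.05.

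Among the genes nearest to the threshold, the ones higher in Anaef were Arhgap35, a GTPase-activating protein (log2 fold change 0.92, adjusted p = 0.289), Laptm4b, a lysosomal membrane protein (2.54, 0.289), and Bcl9, a coactivator of beta-catenin (1.01, 0.302), with the predicted genes Gm38118 (0.88, 0.289) and Gm16867 (0.93, 0.298). On the lower side Phka1, a regulatory subunit of phosphorylase kinase, had 112 counts over the WT libraries and 0 over the Anaef libraries. In total RNA this makes it at least 42.9-fold lower against a floor of 3 counts over the group (adjusted p = 0.145). In RPF it had 3 and 2 counts in WT 1B and 2B and 1 and 1 in Anaef 3B and 4B. It was thus not absent from the Anaef pools, and these counts are too few for a fold. The predicted genes Gm42427 (-0.95, adjusted p = 0.0753), Gm37416 (-1.23, 0.0879), Gm43305 (-1.15, 0.101) and Gm42428 (-1.60, 0.145) were also lower. None of these 10 passed. Whether the counting took the strand into account is not given in the sources used here, so counts of predicted genes that overlap other transcripts are uncertain.

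The fixed gene lists gave the same lead. The plasma cell list fell, with a median log2 fold change of -1.90, 13 of its 14 tested members lower and an adjusted p of 2.79e-17 by camera (adjusted p = 0.178 with an estimated correlation). Besides Igha, its members with the smallest p were Ighg2b, an IgG heavy chain (-3.82, SE 0.74), Igkc, the constant region of the kappa light chain (-2.33, SE 0.47), and Mzb1, a chaperone of antibody assembly (-5.27, SE 1.06). When adjusted over the list alone 7 members passed, all lower, against 1 over all genes tested. Its most abundant members were Igkc, at 2379 ± 1705 CPM in WT and 473 ± 160 CPM in Anaef, and Ighg2c, at 918 ± 1058 and 94.8 ± 80.6 CPM. The list mean was lower in all 4 Anaef libraries than in any WT library (exact permutation p = 0.0286 two-sided over 70 assignments, n = 4 each, the smallest they allow; adjusted 0.207).

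B cell markers fell as well, with a median of -1.26, 19 of 20 members lower and an adjusted p of 4.56e-11 (adjusted p = 0.201 with an estimated correlation). Examples were Spib, a transcription factor of B cells (-1.95, SE 0.56), Bank1, a scaffold of B cell receptor signalling (-1.86, SE 0.61), and Cr2, the complement receptor CD21 (-1.53, SE 0.57). Ighm, the IgM heavy chain and the most abundant member, went the other way at 746 ± 83.2 CPM in WT and 1053 ± 251 CPM in Anaef (0.50, SE 0.19). Cd74, the invariant chain of MHC class II, was at 55.5 ± 18.6 and 22.2 ± 20.02 CPM. No member passed over all genes tested or when adjusted over the list alone (0 by edgeR), although 7 had an unadjusted p under 0.05, 6 lower and 1 higher. The list mean was 2.46 on the log2 CPM scale in Anaef replicate 7, within the WT range of 2.12 to 3.05, and 0.17 to 0.59 in the other Anaef libraries.

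Markers of follicular and peripheral helper T cells, the CD4+ subsets that help B cells, rose. Their median was 0.44, 19 of 22 members were higher and the adjusted p was 1.74e-05 (adjusted p = 0.356 with an estimated correlation). The exact permutation test of the list mean gave p = 0.0571 (adjusted 0.207). Adjusted over the list alone, Tox, a transcription factor of chronically stimulated and helper T cells, rose from 113 ± 8.21 to 168 ± 19.2 CPM (0.58, SE 0.14). By the same criterion Pou2af1, a coactivator that B cells also express strongly, fell (-1.38, SE 0.37). Neither passed over all genes tested. Sostdc1, a secreted antagonist made by follicular helper cells, was at 2.92 (SE 1.00) and Tnfsf8, the ligand of CD30, at 0.53 (SE 0.18). The list mean in WT replicate 3 was 3.71, the lowest of the 8 libraries, and in Anaef replicate 6 it was 5.03, the highest, so the libraries that stood apart moved with this group.

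Myeloid and dendritic cell markers fell, with a median of -0.75, 10 of 12 members lower and an adjusted p of 0.00143 (adjusted p = 0.201 with an estimated correlation); at a mean of at least 50 counts the call was lost at 0.148, within a range of 9.5e-05 to 0.201 over its alternatives. Mpeg1, the pore protein perforin-2 of phagocytes, was at -1.93 (SE 0.69) and Itgam, the integrin CD11b, at -0.55 (SE 0.22), from 15.1 ± 1.47 to 10.3 ± 1.72 CPM. Xcr1, a receptor of cross-presenting dendritic cells, was at 5.98 ± 1.43 and 6.06 ± 2.02 CPM. CD4 T cell identity genes rose by a small amount, with a median of 0.18, 12 of 18 members higher and an adjusted p of 0.0412 (adjusted p = 0.221 with an estimated correlation). Among them were Themis, a regulator of TCR signalling (0.40, SE 0.13), the costimulatory receptor Cd28 (0.44, SE 0.19) and Cd3e of the TCR complex (0.40, SE 0.17). No member of either list passed over all genes tested or when adjusted over the list alone. The identity call was lost without WT replicate 1 (0.0644), 2 (0.0822) or 4 (0.0516), without Anaef replicate 5 (0.117) or 8 (0.183), and at a mean of at least 50 counts (0.0882). It was also lost with protein-coding genes only (0.0570) and with the coding length trend removed (0.0903), alternatives chosen after seeing the data. With that trend removed the median went only from 0.179 to 0.145, so the lost call does not tie the identity list to coding length. Over its alternatives the adjusted p ran from 0.0068 to 0.221. By the exact permutation test of list means, the B cell, myeloid and CD4 identity lists each had p = 0.0571 (adjusted 0.207). The glycolysis, sterol and CD8 lists, which camera did not call, had the same values by that test.

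**Figure D1:**
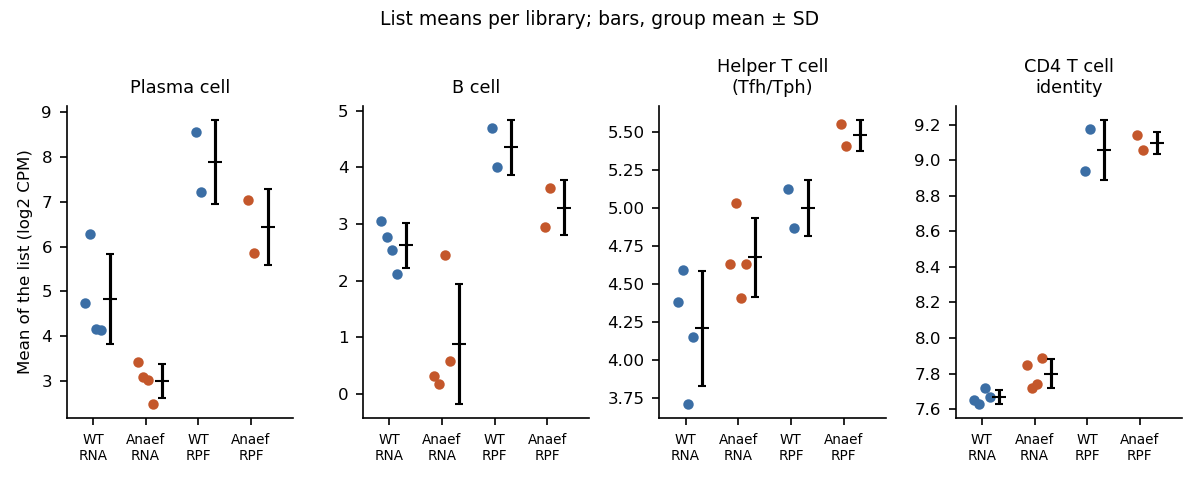
Mean log2 CPM of the tested members of 4 gene lists (y axis) in each library, by genotype and assay (x axis); points are libraries and bars the group mean ± SD. The plasma cell list lay between 2.49 and 3.42 in the Anaef total RNA libraries and between 4.14 and 6.28 in WT, and the helper T cell list between 5.41 and 5.55 in the Anaef RPF pools and between 4.87 and 5.13 in WT.

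Lists of other cell types that did not pass in total RNA were those of CD8 T cells (median -0.33, adjusted p = 0.164), NK and gamma-delta T cells (-0.32, 0.115) and stromal and endothelial cells (0.16, 0.954). Their most abundant members were Cd8b1 at 9.35 and 10.4 CPM and Ctsw at 8.39 and 6.67 CPM in WT and Anaef for CD8 cells, Trdc at 10.5 and 10.6 CPM and Klrd1 at 5.54 and 3.63 CPM for NK and gamma-delta cells, and Pecam1 at 144 and 171 CPM and Vwf at 12.9 and 14.4 CPM for endothelium. Of the erythroid list only Bpgm was tested, at 25.7 and 26.9 CPM. Among T cell state lists the Th1, Th2 and Th17 list came closest and had a median of 0.42 and an adjusted p of 0.0503, with Gata3, the Th2 regulator, at 0.51 (SE 0.20). Anergy and chronic stimulation markers were at 0.15 (0.115; adjusted over the list alone 1 member passed, Tox), regulatory T cell markers at 0.14 (0.615), naive markers at -0.02 (0.528) and activated and memory markers at -0.06 (0.717). Within these, Tcf7, a transcription factor of naive T cells, was at 0.41 (SE 0.12), the adhesion receptor Cd44 at 0.48 (SE 0.19) and the helper ligand Cd40lg at 0.51 (SE 0.17), none passing.

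Signalling lists did not pass in total RNA. Ras-ERK pathway components had a median of 0.00 (adjusted p = 0.542), with the exchange factor Sos1 at 0.51 (SE 0.19) and Rasgrp3, the family member of B cells, at -1.98 (SE 0.61), and mTORC1 components a median of -0.09 (0.669). Immediate early and tonic TCR-responsive genes were at 0.11 (0.756), with Egr1 at -0.46 (SE 0.16), its corepressor Nab2 at -0.70 (SE 0.27) and the phosphatase Dusp1 at 0.83 (SE 0.34). Interferon-stimulated genes were at 0.05 (0.115), with the nucleic acid sensor Zbp1 at 0.68 (SE 0.17) and Ifit1 at 0.61 (SE 0.22). That list passed as higher without WT replicate 1 (0.00147), WT replicate 2 (0.0214) or Anaef replicate 5 (0.0252), within a range of 0.00147 to 0.923 over its alternatives. Sterol synthesis and uptake was at -0.12 (0.275), with Scd1, a fatty acid desaturase, at -2.10 (SE 0.77) and Cyp51, a sterol demethylase, at -0.63 (SE 0.28). The remaining medians were 0.07 for spliceosome components (0.0648), -0.41 for the cell cycle (0.115), -0.08 for glycolysis (0.481), -0.06 for heat shock (0.528) and -0.02 for the ATF4 and amino acid response (0.889). They were 0.03 for cytosolic ribosomal proteins (0.2997), 0.01 for translation factors of the TOP class (0.954), -0.04 for mitochondrial ribosomal proteins (0.719), 0.05 for nuclear oxidative phosphorylation (0.449), 0.02 for mitochondrially encoded genes (0.528) and -0.04 for proteasome subunits (0.889). Leaving out 1 library made several of these lists pass in the direction of their test. Without WT replicate 3 these were cytosolic ribosomal proteins (3.82e-09), mitochondrially encoded genes (1.23e-07), oxidative phosphorylation (0.00186), the cell cycle (0.00331) and spliceosome components (0.0107). The Th1, Th2 and Th17 list passed without WT replicate 1 (0.0134) or 2 (0.0057) or Anaef replicate 5 (0.0337), 7 (0.0269) or 8 (0.00866). The cell cycle list also passed without WT replicate 4 (0.0343) or Anaef replicate 6 (0.0360) or 8 (0.0390), and spliceosome components without WT replicate 2 (0.0446) or Anaef replicate 5 (0.0473). Without Anaef replicate 6 cytosolic ribosomal proteins (0.00365), anergy markers (0.0423) and CD8 markers (0.0423) passed, and without WT replicate 2 anergy markers (0.0214). The camera test pointed higher while the median lay below 0 for the naive, activated, mitochondrial ribosomal and proteasome lists, and lower while it lay above 0 for the TOP list. For the ATF4 list the mean (0.13) lay above 0 with the median and the test below, and for the Ras-ERK (-0.02) and stromal (-0.16) lists the mean lay below 0 with the test above.

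The RPF comparison addresses which mRNAs were bound by more or fewer ribosomes in Anaef. Helper T cell and regulatory T cell lists were higher in the 2 Anaef pools and B-lineage lists were lower at the preset correlation of camera, with an adjusted p of 0.399 to 0.411 with an estimated correlation. Interferon and respiratory chain lists were also higher, but the interferon call was lost without WT 2B and the respiratory chain call with the coding length trend removed. No single gene out of 9710 tested passed (0 by edgeR, smallest adjusted p 0.296), with 1151 at an unadjusted p under 0.05, 56 called by DESeq2 (9 higher, 47 lower) and 0 by limma-voom. Of 28 lists tested, 15 passed at the preset correlation of camera, 9 higher and 6 lower, and none (0) with an estimated correlation or by fry. An exact permutation test of 2 pools against 2 cannot go below p = 0.333, so the 15 calls compare lists with other genes and rest on 4 pools.

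Helper T cell markers rose in RPF, with a median of 0.43, 19 of 22 members higher and an adjusted p of 1.03e-06 (adjusted p = 0.399 with an estimated correlation). When adjusted over the list alone 9 members passed, 8 higher and 1 lower, against 0 over all genes tested. Pdcd1, the inhibitory receptor PD-1, rose by that criterion from 25.5 ± 3.46 to 50.0 ± 2.65 CPM (n = 2 each; 0.98, SE 0.19). Sostdc1 was at 1.79 (SE 0.36), Tox2, a transcription factor of follicular helper cells, at 1.36 (SE 0.30) and Sh2d1a, the adaptor SAP, at 0.56 (SE 0.15), all passing over the list alone. In the related anergy list, which holds Pdcd1 and Tox as well, the median was 0.16 and the adjusted p 0.0282 (adjusted p = 0.399 with an estimated correlation), and only Pdcd1 passed over the list alone, with Tox at 0.39 (SE 0.15). That call was lost without WT 2B (0.396), Anaef 3B (0.176) or Anaef 4B (0.114).

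Regulatory T cell markers rose too, with a median of 0.37, 10 of 12 members higher and an adjusted p of 0.00359 (adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone 2 members passed, Tnfrsf4, the costimulatory receptor OX40, from 23.5 ± 0.603 to 40.2 ± 1.56 CPM (0.77, SE 0.17) and Ikzf2, the transcription factor Helios (0.82, SE 0.20); Tnfrsf18, known as GITR, was at 0.60 (SE 0.18) and Ctla4 at 0.45 (SE 0.19). The Th1, Th2 and Th17 list had a median of 0.43 and an adjusted p of 0.00492 (adjusted p = 0.399 with an estimated correlation). Over that list alone 2 of its 9 tested members passed, the chemokine receptors Ccr4 (0.89, SE 0.19) and Ccr6 (1.51, SE 0.39). The call was lost without WT 2B (0.0946) or Anaef 3B (0.120). Activated and memory markers were at 0.13 (adjusted p = 0.0376, and adjusted p = 0.440 with an estimated correlation), with the calcium-binding proteins S100a11 at 0.67 (SE 0.16) and S100a6 at 0.99 (SE 0.24), 0 members passing over the list alone. Without WT 2B (0.465), Anaef 3B (0.151) or Anaef 4B (0.0619) that call was lost. With the coding length trend removed it was lost as well (0.174), although the median changed little, from 0.13 to 0.11.

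Interferon-stimulated genes rose in RPF, with a median of 0.21 and 32 of 38 members higher (adjusted p = 0.0018, and adjusted p = 0.601 with an estimated correlation). Examples were the antiviral GTPase Mx1 (1.49, SE 0.40), the immunity-related GTPase Igtp (0.60, SE 0.19) and the tethering protein Bst2 (0.36, SE 0.14), 0 passing over the list alone. The call rested on WT 2B, without which the adjusted p was 0.722, the top of a range that began at 2.34e-09 over its alternatives. Heat shock genes fell, with a median of -0.32 and 11 of 14 members lower (adjusted p = 0.0119, and adjusted p = 0.399 with an estimated correlation). Over the list alone 2 passed, the mitochondrial chaperonin Hspd1 (-0.76, SE 0.16) and the co-chaperone Dnaja1 (-0.68, SE 0.16), and the list call was lost without WT 2B (0.270) or Anaef 3B (0.230).

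Among lists of the translation and energy machinery, nuclear oxidative phosphorylation rose most clearly, with a median of 0.33, 56 of 74 members higher and an adjusted p of 1.03e-06 (adjusted p = 0.399 with an estimated correlation). Examples were the ATP synthase subunits Atp5l (0.71, SE 0.15) and Atp5f1 (1.23, SE 0.33), Ndufa1 of complex I (0.77, SE 0.17) and Cox6b1 of complex IV (0.52, SE 0.13), 0 passing over the list alone. Mitochondrial ribosomal proteins were at 0.14 (0.00861, and adjusted p = 0.399 with an estimated correlation), with Mrps33 at 0.86 (SE 0.26) and Mrpl14 at 0.99 (SE 0.30). Cytosolic ribosomal proteins were at 0.11 (0.0282, and adjusted p = 0.454 with an estimated correlation), with Rpl35a at 0.70 (SE 0.17) and Rpl4 at -0.53 (SE 0.13). Translation factors of the TOP class, whose mRNAs carry the same pyrimidine tract as ribosomal protein mRNAs, fell, with a median of -0.18 and 22 of 27 members lower (0.0282, and adjusted p = 0.399 with an estimated correlation). Among these were the chaperonin subunit Cct4 (-0.60, SE 0.13), the ribosomal scaffold Rack1 (-0.64, SE 0.18), the nucleotide synthesis enzyme Impdh2 (-0.49, SE 0.15) and the elongation factor Eef1a1 (-0.39, SE 0.15). Sterol synthesis and uptake fell, with a median of -0.26 and 20 of 26 members lower (0.0314, and adjusted p = 0.560 with an estimated correlation), with Cyp51 at -0.58 (SE 0.17) and Scd1 at -0.53 (SE 0.17). Over each of these 4 lists alone 0 members passed.

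The RPF fold change varied with the length of the coding sequence. Its median was 0.31 in the shortest of 10 bins of genes (111 to 525 nucleotides, 851 genes), -0.12 in bin 5 and 0.14 in the longest, while in total RNA the medians of the bins lay between 0.01 and 0.07. Oxidative phosphorylation genes had a median coding length of 426 nucleotides against 1395 over all genes. With the length trend removed from each library, an alternative chosen after seeing the data, the call was lost for oxidative phosphorylation (0.392, within a range of 1.79e-07 to 0.399 over its alternatives), mitochondrial ribosomal proteins (0.380), TOP factors (0.143) and sterol synthesis (0.0697), and cytosolic ribosomal proteins turned lower (0.176). The median went from 0.33 to 0.03 for oxidative phosphorylation, from 0.14 to 0.02 for mitochondrial ribosomal proteins, from 0.11 to -0.06 for cytosolic ribosomal proteins and from -0.18 to -0.11 for TOP factors. For sterol synthesis it went only from -0.26 to -0.23 (95% bootstrap interval -0.41 to -0.03), so the lost call does not tie that list to coding length. Under the same alternative proteasome subunits (0.0143) and CD8 markers (0.0456) passed, which left 11 lists. At a mean of at least 50 counts 11 lists also passed, since the TOP (0.0539) and sterol (0.0539) calls were lost and the erythroid list and the Th1, Th2 and Th17 list had too few members for a test. The call for cytosolic ribosomal proteins was also lost without WT 1B (0.0984), WT 2B (0.0777) or Anaef 3B (0.219), that for mitochondrial ribosomal proteins without WT 1B (0.0507) or Anaef 4B (0.105), and that for TOP factors without WT 1B (0.0713), WT 2B (0.0901), Anaef 3B (0.110) or Anaef 4B (0.0954). Sterol synthesis lost its call without WT 2B (0.509), Anaef 3B (0.174) or Anaef 4B (0.114).

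**Figure D2:**
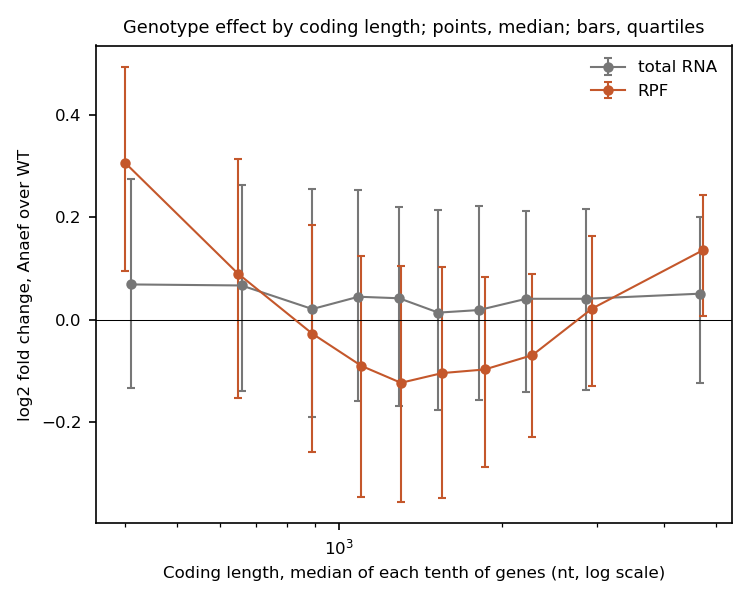
Median log2 fold change of Anaef over WT (y axis) in 10 bins of genes ordered by coding length in nucleotides (x axis, log scale), for total RNA and RPF; points are medians and bars the quartiles of each bin. In RPF the median was 0.31 in the shortest bin and -0.12 in bin 5, while total RNA stayed between 0.01 and 0.07.

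B-lineage RNA was lower in the RPF pools as well. Plasma cell markers fell, with a median of -1.73 and 13 of 14 members lower (adjusted p = 2.56e-08, and adjusted p = 0.411 with an estimated correlation). Jchain, which links IgA and IgM into polymers, was at 1142 ± 503 CPM in WT and 308 ± 228 CPM in Anaef (-1.89, SE 0.54), Igha at -1.60 (SE 0.46), Igkc at -2.22 (SE 0.68) and Sdc1, the plasma cell surface marker CD138, at -2.26 (SE 0.71). B cell markers fell, with a median of -1.21 and all 13 members lower (7.78e-08, and adjusted p = 0.399 with an estimated correlation), including Bank1 (-1.46, SE 0.46), the IgM receptor Fcmr (-1.54, SE 0.49) and the receptor component Cd79b (-1.49, SE 0.52). The size of these RPF folds depended on single pools, although their direction did not change under any alternative run. Over the alternatives the fold of Jchain ran from -2.96 to -1.29, of Igha from -2.62 to -1.01, of Igkc from -3.13 to -1.003, of Sdc1 from -3.17 to -1.15, of Fcmr from -2.28 to -1.002, of Bank1 from -1.93 to -1.06 and of Cd79b from -2.03 to -0.51. The plasma cell list mean was 8.55 in WT 1B and 7.22 in WT 2B, close to the 7.04 of Anaef 3B, and 5.85 in Anaef 4B. The most abundant members of the B cell list, Ighm at -0.42 (SE 0.51) and Cd74 at -0.44 (SE 0.25), were less different. Erythroid markers fell, with a median of -1.40 and 4 of 5 members lower (0.00999, and adjusted p = 0.399 with an estimated correlation), at a low level, with the beta globin Hbb-bs at 4.87 ± 2.09 and 1.83 ± 1.36 CPM; without WT 1B (0.0984) or Anaef 3B (0.356) that call was lost. Over each of these 3 lists alone 0 members passed. The myeloid list (3 members tested) and the stromal list (2 tested) were too small for a test, with Cst3 at 55.8 and 80.3 CPM, Acta2, the smooth muscle actin, at 1204 and 724 CPM and Pecam1 at 168 and 151 CPM in WT and Anaef. Acta2 passed over the stromal list alone (-0.73, SE 0.15).

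The lists that did not pass in RPF included naive T cell markers, with a median of -0.22 and an adjusted p of 0.0737. Over that list alone 6 members passed, 5 lower and 1 higher. They included the transcription factors Klf3 (-1.02, SE 0.18), Lef1 (-0.53, SE 0.12) and Tcf7 (-0.53, SE 0.14) and, higher, the gut-homing receptor Ccr9 (0.93, SE 0.25). Ras-ERK components were at -0.04 (0.591), with Map2k1, a kinase of the cascade, at -0.52 (SE 0.16). CD4 T cell identity was at 0.00 (0.591), mTORC1 components at 0.05 (0.632), immediate early genes at 0.14 (0.512), the cell cycle at 0.01 (0.856), glycolysis at -0.04 (0.778, with Gapdh at -1.16, SE 0.25) and the ATF4 response at -0.12 (0.632). Spliceosome components were at 0.09 (0.106) and proteasome subunits at 0.07 (0.0560), with 1 member each passing over the list alone. Mitochondrially encoded genes were at 0.14 (0.581), CD8 markers at -0.11 (0.0685, Crtam passing over the list alone), with Ctsw at 101 and 78.0 CPM and Cd8b1 at 17.4 and 16.1 CPM, and NK and gamma-delta markers at -0.26 (0.213), with Prf1 at 84.4 and 65.5 CPM and Trdc at 24.9 and 20.9 CPM. For mTORC1 components the median was above 0 while the mean (-0.03) and the test pointed lower, and for the cell cycle the mean was -0.01. Without WT 1B the naive (0.0120), cell cycle (0.0171), CD8 (0.0171) and spliceosome (0.0324) lists passed, and without Anaef 3B spliceosome components did (0.0167). Mitochondrially encoded genes passed as higher without Anaef 4B (1.71e-16) and as lower without Anaef 3B (3.504e-07).

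Single genes nearest to the threshold in RPF were, on the lower side, Klhdc2, a substrate receptor of a ubiquitin ligase (61.8 ± 4.66 to 20.2 ± 0.985 CPM, -1.61, SE 0.18), the ketone body enzyme Oxct1 (-1.25, SE 0.15), the G protein subunit Gnb1 (-1.32, SE 0.18), the mitochondrial transhydrogenase Nnt (-1.54, SE 0.22) and the segment Ighv1-49 (-2.43, SE 0.35). On the higher side were the motor protein Myo6 (21.1 ± 2.08 to 71.3 ± 12.1 CPM, 1.76, SE 0.20), Snrpb, a core protein of the spliceosome (1.42, SE 0.18), Psma3, an alpha subunit of the proteasome (1.66, SE 0.26), the protease inhibitor Stfa3 (3.40, SE 0.55, at 0.464 and 5.10 CPM) and the predicted gene Gm9797 (1.56, SE 0.29). Their adjusted p lay between 0.296 and 0.344, and none passed. Without mitochondrial, Ig and TCR genes 6 passed, namely Klhdc2, Oxct1, Gnb1 and Nnt, which were lower, and Myo6 and Snrpb, which were higher. The count was 514 with no filter on low counts, 211 without Anaef 3B, 14 without Anaef 4B and 1 without WT 2B.

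The translational efficiency comparison addresses whether ribosome occupancy changed by more or less than the transcript, as the interaction of genotype and assay over the 12 libraries. Naive T cell markers were the list with the clearest shift. Their RPF was lower relative to their total RNA in Anaef, with a median of -0.18, 15 of 20 members lower and an adjusted p of 0.000415 (adjusted p = 0.329 with an estimated correlation). Over the list alone 3 members passed, all lower, against 0 over all genes tested. Tcf7 was at -0.95 (SE 0.19), with total RNA at 1153 ± 35.01 and 1533 ± 155 CPM and RPF at 627 ± 71.5 and 432 ± 3.24 CPM in WT and Anaef on the scale of this fit. Klf3 was at -1.29 (SE 0.30) and Lef1 at -0.73 (SE 0.22).

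Translation factors of the TOP class fell in efficiency, with a median of -0.16 and 21 of 27 members lower (0.0139, and adjusted p = 0.645 with an estimated correlation), including Cct4 (-0.81, SE 0.28), the histone chaperone Nap1l1 (-0.51, SE 0.28) and the initiation factors Eif3e (-0.57, SE 0.32) and Eif4b (-0.30, SE 0.19), 0 passing over the list alone. The cell cycle list rose, with a median of 0.36 and 21 of 30 members higher (0.0139, and adjusted p = 0.607 with an estimated correlation). In the separate fits its median was -0.41 in total RNA and 0.01 in RPF, and it passed in neither. The shift therefore lay on the side of total RNA and not in more footprints. Over that list alone 2 passed, the thymidylate synthase Tyms (1.58, SE 0.41) and the mitotic kinase Cdk1 (4.22, SE 1.14), the latter with 0.068 CPM in Anaef total RNA; Ccna2 was at 2.88 (SE 1.38) and Uhrf1, which maintains DNA methylation, at 0.73 (SE 0.36). Nuclear oxidative phosphorylation rose, with a median of 0.16 and 51 of 75 members higher (0.0410, and adjusted p = 0.860 with an estimated correlation), including Atp5f1 (1.03, SE 0.39), Atp5j (0.65, SE 0.27), Ndufa7 (1.51, SE 0.61) and Ndufa1 (1.52, SE 0.67), 0 passing over the list alone. With the length trend removed the calls for oxidative phosphorylation (0.876) and TOP factors (0.162) were lost. The count stayed at 4 lists, 3 higher and 1 lower, since other lists, not named here, then passed as higher. The oxidative phosphorylation call was also lost without total RNA WT 2 (0.111), WT 3 (0.985), Anaef 5 (0.0906), Anaef 6 (0.230) or Anaef 7 (0.117), RPF WT 1B (0.268) or Anaef 4B (0.122), the cell cycle call without total RNA WT 2 (0.180) or Anaef 5 (0.0591) or RPF WT 2B (0.351), and the TOP call without total RNA Anaef 8 (0.119). At a mean of at least 50 counts the cell cycle and TOP calls were lost (0.0736 each). With protein-coding genes only the cell cycle (0.0557), TOP (0.0566) and oxidative phosphorylation (0.0566) calls were lost, and with the GC trend removed the TOP call (0.0563).

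No single gene of 19031 passed for translational efficiency (0 by edgeR, smallest adjusted p 0.418), with 636 at an unadjusted p under 0.05, 12 called by DESeq2 (5 higher, 7 lower) and 0 by limma-voom. The smallest p belonged, on the lower side, to Gnb1 (-1.57, SE 0.24), the Golgi protein Casc4 (-2.63, SE 0.52), Tcf7, the stress kinase Oxsr1 (-2.68, SE 0.56) and Oxct1 (-1.37, SE 0.30). On the higher side they were Cnot6l, a deadenylase (1.44, SE 0.25), Psma3 (1.55, SE 0.31) and, near zero counts, Igkv5-48, with 2 counts in Anaef total RNA, and Gm21411 and Cyp2u1, both with 0 WT RPF counts. For the last 3 the fitted fold is no bound and is left out. The self-test on simulated data recovered 6% of genes with a log2 change of 2 in this comparison and 28% at a log2 change of 3. Averaged over all genes of the comparison, most changes of that size or smaller in single genes would therefore be missed. The simulation tested 18553 genes here and 9557 in RPF, so these shares include genes with few footprints. Recovery for genes with more footprints was not measured apart.

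The other lists did not pass for translational efficiency. Ras-ERK components had a median of -0.06 (adjusted p = 0.186), with the GTPase Nras at 1.30 (SE 0.38). Heat shock was at -0.20 (0.0665, with Hspd1 at -0.70, SE 0.23), CD4 T cell identity at -0.18 (0.186), the Th1, Th2 and Th17 list at 0.00 (0.926, with Gata3 at -0.63, SE 0.29), helper T cell markers at 0.05 (0.991), anergy markers at -0.01 (0.863), regulatory T cell markers at 0.02 (0.255) and activated markers at 0.14 (0.318). Interferon-stimulated genes were at 0.13 (0.255), immediate early genes at 0.01 (0.780), mTORC1 components at 0.09 (0.870), the sterol list at -0.05 (0.592), glycolysis at 0.01 (0.560) and mitochondrially encoded genes at 0.04 (0.991). Cytosolic ribosomal proteins were at 0.11 (0.761), mitochondrial ribosomal proteins at 0.16 (0.318), spliceosome components at 0.00 (0.557) and proteasome subunits at 0.06 (0.248; over the list alone 1 member, Psma3, passed). B cell markers were at 0.35 (0.451), plasma cell markers at 0.15 (0.363), CD8 markers at -0.16 (0.592), NK and gamma-delta markers at 0.52 (0.592) and myeloid markers at 0.62 (0.0665). With members near zero counts set to their bounds, the medians were 0.18 for the ATF4 response (0.972), 0.83 for stromal markers (0.110) and 1.05 for erythroid markers (0.141). The test pointed lower while the median lay above 0 for the mTORC1, mitochondrially encoded, immediate early, spliceosome and Th1, Th2 and Th17 lists. The ATF4 and stromal lists had fitted medians of -0.13 and -0.17, in the direction of the test and opposite to the medians at bounds. Leaving out 1 library made many of these lists pass. Without RPF WT 1B these were interferon-stimulated genes (0.000122), CD4 T cell identity (0.000418), plasma cell (0.000626), myeloid (0.0113), heat shock (0.0147), Ras-ERK (0.0328), B cell (0.0370) and sterol (0.0465) lists. Without RPF Anaef 4B heat shock (0.00286) and plasma cell markers (0.00223) passed and mitochondrially encoded genes passed as higher (1.19e-05), and without Anaef 3B myeloid markers (0.00796) and, as lower, mitochondrially encoded genes (1.18e-07). Without total RNA WT 1 cytosolic ribosomal proteins (0.0173), heat shock (0.0296) and erythroid markers (0.0296) passed. Without WT 3 myeloid markers (0.0259), CD4 T cell identity (0.0369), Ras-ERK components (0.0371), stromal markers (0.0371) and mitochondrially encoded genes (0.0188) passed, and cytosolic ribosomal proteins passed as lower (0.00129). Without WT 4 heat shock (0.0157), interferon-stimulated genes (0.0158), myeloid (0.0390), plasma cell (0.0431), proteasome (0.0431) and erythroid (0.0431) lists passed. Without Anaef 5 heat shock passed (0.00902), and without Anaef 7 B cell (0.00153) and myeloid (0.0374) markers.

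The ratio of RPF to total RNA in the 6 WT libraries addresses the baseline without the mutation. Relative to other genes, the ratio was high for mRNAs of energy metabolism and protein turnover and low for mitochondrially encoded mRNAs. Differences between the assays in library kit, poly-A capture and masking are part of this ratio, for single genes and for lists alike, so it is not a measure of translation alone. Of 30 lists 15 passed, 14 higher and 1 lower, 0 with an estimated correlation and 17 by fry. Of the 15, 14 also passed in the 6 Anaef libraries. Over all genes the median ratio was -1.62 on the log2 scale, and over protein-coding genes -0.36.

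Nuclear oxidative phosphorylation had a median ratio of 1.57 (adjusted p = 3.32e-14, and adjusted p = 0.343 with an estimated correlation), with Sdhb of complex II at 2.99 (SE 0.18) and Uqcrc2 of complex III at 2.42 (SE 0.16). Proteasome subunits were at 1.72 (1.66e-09, and adjusted p = 0.343 with an estimated correlation), with the immunoproteasome subunit Psmb10 at 4.36 (SE 0.20) and Psma3 at -3.84 (SE 0.23). Glycolysis was at 1.59 (3.76e-06, and adjusted p = 0.167 with an estimated correlation), with the pyruvate kinase Pkm at 3.25 (SE 0.13). Mitochondrial ribosomal proteins were at 0.90 (2.98e-07, and adjusted p = 0.343 with an estimated correlation) and spliceosome components at 0.63 (5.61e-07, and adjusted p = 0.343 with an estimated correlation). Sterol synthesis was at 0.69 (0.0011), heat shock at 0.88 (0.00131) and immediate early genes at 0.27 (0.00501), each with an adjusted p = 0.343 with an estimated correlation. Among these were the heat shock protein Hsp90aa1 at 3.50 (SE 0.19) and the transcription factor Junb at 4.05 (SE 0.28).

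The CD4 identity, activated and memory and cell cycle lists were also high in WT, as were the interferon and plasma cell lists. The helper, anergy, regulatory and Th1, Th2 and Th17 lists did not pass. CD4 T cell identity was at 0.73 (0.000642, and adjusted p = 0.388 with an estimated correlation), with the kinase Zap70 at 3.27 (SE 0.17) and Cd3g at 2.24 (SE 0.15). Activated and memory markers were at 0.96 (0.000642, and adjusted p = 0.343 with an estimated correlation), interferon-stimulated genes at 0.73 (0.000642, and adjusted p = 0.454 with an estimated correlation) and the cell cycle at 1.56 (0.000642, and adjusted p = 0.400 with an estimated correlation). Plasma cell markers were at 2.56 (0.000642, and adjusted p = 0.415 with an estimated correlation), with Igha at 3.78 (SE 0.19). Naive markers passed as higher (0.0441, and adjusted p = 0.343 with an estimated correlation) although their median was -0.15, with the transcription factor Klf2 at 4.76 (SE 0.35) and Klf3 at -2.11 (SE 0.16), and lost the call in the Anaef libraries (0.258) and without total RNA WT 2 (0.0639) or WT 4 (0.0529). Mitochondrially encoded genes were at -5.79, all 13 lower (0.000642, and adjusted p = 0.454 with an estimated correlation), with mt-Co1 at -5.10 (SE 0.30); their RNA is translated by the ribosomes of the organelle. Against protein-coding genes alone, an alternative chosen after seeing the data, 8 lists passed and the calls were lost for sterol synthesis (0.0534), immediate early genes (0.171), naive markers (0.371), interferon-stimulated genes (0.0519), CD4 T cell identity (0.0923) and plasma cells (0.339).

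Several signalling genes had few footprints for their RNA. Nras was at -8.17 (SE 0.26), the exchange factor Rasgrp2 at -3.20 (SE 0.21), Rasgrp1 at -2.36 (SE 0.20) and Eif4ebp2, a repressor of cap-dependent initiation, at -5.49 (SE 0.24). The Ras-ERK list had a median of -0.93 and did not pass by camera (adjusted p = 0.582), and the mTORC1 list a median of -0.52 (0.367). By fry both passed as lower, with an adjusted p of 0.00015 and 0.0082. The RPF columns were masked in a way the sources used here do not state, and 87 of 6486 protein-coding genes with at least 10 CPM in total RNA had 0 RPF counts, so low ratios of single genes are uncertain. The other lists did not pass, with medians of -0.54 for cytosolic ribosomal proteins (0.190), 0.38 for TOP factors (0.0624), 0.21 for the ATF4 response (0.0916), -0.44 for helper T cell markers (0.110), 0.06 for anergy (0.110), 0.11 for regulatory T cells (0.202) and 0.06 for the Th1, Th2 and Th17 list (0.205). They were -0.49 for B cells (0.190), 0.89 for CD8 T cells (0.0507), 0.23 for NK and gamma-delta T cells (0.0504), 0.23 for myeloid cells (0.202) and, with members near zero at their bounds, -1.55 for stromal cells (0.274). For erythroid cells the median was 2.21 (0.240). The test sets a list against all other genes, whose median was -1.62, so it pointed higher for the cytosolic ribosomal proteins, helper T cell, B cell, mTORC1 and stromal lists although their medians were negative. Lists that passed with 1 library left out were TOP factors (0.0412) and NK and gamma-delta markers (0.0321) without RPF 2B, CD8 markers (0.0272) without RPF 1B, NK and gamma-delta markers (0.0492) without total RNA WT 4 and erythroid markers (0.0248) without total RNA WT 3.

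Setting the total RNA effect beside the RPF effect addresses whether transcripts and footprints changed alike. Most B-lineage genes named here were lower in both assays, and several helper T cell genes were higher in both, none of the latter passing over all genes tested in either. Jchain was at -1.81 in total RNA and -1.89 in RPF, Igha at -1.98 and -1.60, Bank1 at -1.86 and -1.46 and Mzb1 at -5.27 and -2.20. The kappa segments that passed in total RNA fell by much less in RPF. Igkv4-72 was at -5.62 and -1.86 and Igkv6-17 at -5.84 and -1.65. Igkv5-48, with 2 counts in Anaef total RNA, was at -2.33 in RPF. Sostdc1 was at 2.92 and 1.79, Tox2 at 1.19 and 1.36, Tox at 0.58 and 0.39 and Myo6 at 1.37 and 1.76. Tcf7 went opposite ways, at 0.41 in total RNA and -0.53 in RPF, as did Ighm, the most abundant B cell marker, at 0.50 and -0.42.

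Over 9487 genes the log2 fold changes of the assays had a Pearson correlation of 0.324 and a Spearman correlation of 0.108, and 53.3% had the same sign. At an unadjusted p under 0.05 in both assays there were 141 genes, of which 124 had the same sign. These were 30 higher and 94 lower, where independent assays would give 15.2 and 21.6. Most of the genes lower in both were Ig genes, which may share reads and move together. The excess on the lower side is therefore no count of separate changes. The RPF pools were made from the remaining cells of such samples, so differences between samples may be shared by both assays and raise these counts without an effect of genotype. Without the lists of other cell types and without Ig and TCR segments, an alternative chosen after seeing the data, the Pearson correlation was 0.093. It was 0.191 without RPF WT 1B and 0.214 without RPF Anaef 4B, over a range of 0.093 to 0.439 over its alternatives.

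**Figure D3:**
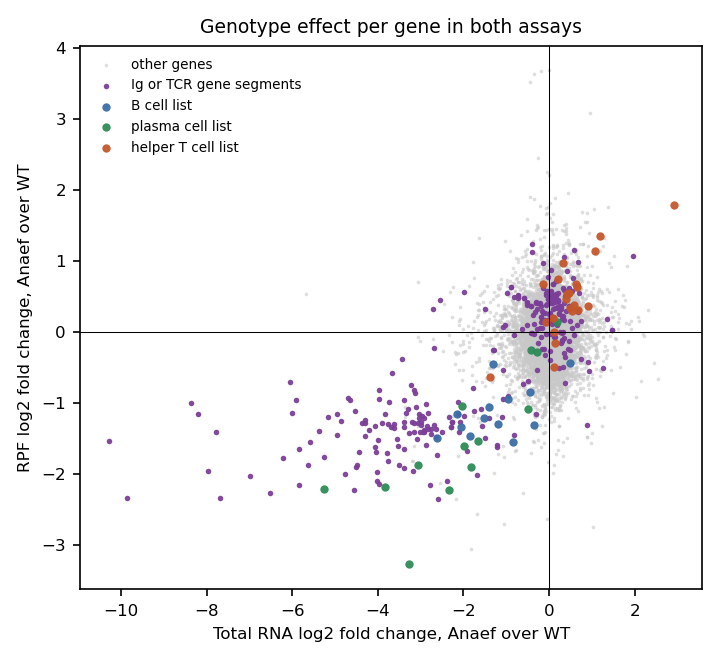
Log2 fold change of Anaef over WT in RPF (y axis) against total RNA (x axis); each of the 9487 points is a gene, coloured for Ig and TCR segments and the B cell, plasma cell and helper T cell lists. The Pearson correlation was 0.324 over all genes.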

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

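The tests of how many lists and genes other splits of the libraries call were planned, and the tests of each called list under other splits, of B-lineage and NK and CD8 medians, of helper against identity genes, and of coding length and GC content were chosen only after the result was seen. Single libraries far from the others of their group were looked for in 110 groups of 4 libraries, and 5 were found where chance gives 5.5, about 1 in 20 groups. Their number is therefore no more than chance would give. The items come from the same libraries and are not independent, so this count does not clear any single library. WT replicate 3 lay at -107.7 on the second component of total RNA, against 19.2 to 25.6 in the other WT libraries. Its correlations with them were 0.906 to 0.910, against 0.953 to 0.962 among them. In WT replicate 3 the pseudogene share was 28.2% against 21.1% to 22.3% in the others, a gap of 0.834 of the group's range. In the same library Rasgrp1 was at 610 CPM against 453 to 479 CPM, a gap of 0.831. Gm42427 was lowest in WT replicate 4, at 1055 CPM against 1279 to 1323 CPM, a gap of 0.837. Mpeg1 was highest in Anaef replicate 5, at 1.27 CPM against 0.172 to 0.344 CPM, a gap of 0.843, and Cd3e in Anaef replicate 6, at 1070.2 CPM against 681 to 713 CPM, a gap of 0.919.

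The genotype effect differed between the assays for 4 lists by the test of the interaction. The adjusted p was 0.000415 for naive markers and 0.0139 for TOP factors, both lower in RPF relative to total RNA. It was 0.0139 for the cell cycle and 0.0410 for nuclear oxidative phosphorylation, both higher. None passed with an estimated correlation (0 of 30).

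Of the 35 splits of the 8 total RNA libraries into 4 and 4, 22 called as many lists as the real split, with 5 lists in the real split and up to 10 in another. Chance is therefore not excluded for the number of lists. The split with 10 lists set WT 1, 2 and 3 and Anaef 8 against the rest, and no split called a list with an estimated correlation (0 in each of the 35). A structure of the samples apart from genotype, or correlation between genes above the preset, could give the extra calls, and these were not told apart by a test. For genes, 2 of 35 splits called as many, with 4 in the real split and 9 in the highest other, so chance is not excluded there either. A camera p as small as the real one came from 1 of 35 splits for the plasma cell list, the real one alone (9.62e-19 against 1.34e-11). It came from 2 of 35 for the B cell list (3.14e-12 against 1.53e-19 in another split) and 4 of 35 for the helper T cell list (1.8e-06 against 1.96e-11). The myeloid list gave 2 of 35 (0.000197 against 0.000151) and the CD4 identity list 2 of 35 (0.0071 against 0.00481), so chance is not excluded for these 4 lists. For the plasma cell list, 1 of 35 is the smallest share these splits allow. That list was picked for the test after its result was seen, so the test cannot exclude chance for it either.

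B cell and plasma cell transcripts were lower in Anaef in both assays. The non-Ig B-lineage genes here are the members of the B cell and plasma cell lists without the Ig genes. These lists hold Prdm1 and Irf4, which activated T cells also express, so not every member is specific to the B lineage. The non-Ig genes had a median log2 fold change of -1.359 in total RNA (95% bootstrap interval -1.721 to -0.901), with 25 of 26 lower. The difference is thus not limited to Ig segments that may share reads. The difference to the median of the NK and CD8 members was -1.032 (-1.514 to -0.467). These intervals resample genes and not libraries, so they cannot exclude a lower share of every other cell type alike. The list means of CD8 (-0.617), NK and gamma-delta (-0.648) and stromal markers (-0.125) fell too, by less than that of B cells (-1.738). Myeloid and dendritic markers fell as well, with a median of -0.75 (-1.345 to -0.155). A joint loss of B-lineage, myeloid and other cells stays open. A smaller share of B-lineage cells, or of their RNA, among the Anaef cells is a candidate explanation. Against it stands Anaef replicate 7, whose B cell list mean of 2.46 lay within the WT range of 2.12 to 3.05. Ighm, the most abundant B cell marker, went the other way in total RNA, at 746 CPM in WT and 1053 CPM in Anaef. It lay far above Cd74, the next member, at 55.5 and 22.2 CPM. Whether the Ighm reads came from B cells was not tested. Whether the genotype or the purity of each bead isolation set such a share stays open, since the design gives no separate measure of purity.

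Helper T cell genes were higher in Anaef in both assays. RNA of B-lineage cells was argued against, since those genes were lower, with a median of -1.284 in RPF (-1.487 to -1.047). The helper median minus the identity median was 0.428 (0.185 to 0.659) in RPF and 0.264 (-0.043 to 0.524) in total RNA. These intervals resample genes and not libraries, so they do not exclude a larger share of CD4 T cells. Coding length was argued against by an RPF median of 0.415 (0.250 to 0.618) with the length trend removed, against 0.43 before. A larger share of helper cells, or higher expression per cell, may underlie the pattern as a hypothesis. Both stay open, as does chance, since 4 of 35 splits gave a p as small in total RNA.

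Nuclear oxidative phosphorylation genes were higher in the Anaef RPF pools, with a median of 0.33 (0.23 to 0.40). With the coding length trend removed the median was 0.032 (-0.037 to 0.077) and the adjusted p 0.392, so the call ended because the fold itself went to near 0. A GC trend was argued against, since the median was 0.333 (0.241 to 0.370) with it removed. A length bias between the RPF libraries is a candidate explanation. By removal of the trend it would cover nearly all of the pattern. By comparison with 809 other genes of similar length, whose median was 0.234 against 0.33, it would cover only a part. Against the mean of the RPF libraries, the rank correlation with coding length was 0.110 in WT 1B and 0.012 in WT 2B. It was -0.017 in Anaef 3B and -0.104 in Anaef 4B. Depth fell in the same order, so depth and genotype cannot be told apart here. The rank correlation with GC content was -0.367 in WT 1B and 0.284 in WT 2B. It was 0.008 in Anaef 3B and 0.092 in Anaef 4B. By GC content the WT pools thus lay at opposite ends, further apart than any pools by coding length. WT 2B correlated with Anaef 3B (0.972) about as well as with WT 1B (0.974). What made the libraries differ by length, technical or biological, stays open.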

How the results depend on the processing

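The alternatives with nuclear protein-coding genes only, RLE for lists, the length and GC trends, and the correlation without Ig and TCR segments were chosen only after the result was seen; the other alternatives were planned. The cause was not tested for any change below, except where fewer genes or libraries were used by construction. For total RNA genes the count of 4 became 166 with DESeq2 (42 higher, 124 lower), 2 with limma-voom, 1 with 1 surrogate variable, 0 without mitochondrial, Ig and TCR genes and 0 with protein-coding genes only, which leave out the genes that passed, and 0 to 3 with each library left out. For RPF genes the count of 0 became 56 with DESeq2, 514 with no filter, 6 without mitochondrial, Ig and TCR genes, 6 with protein-coding genes only and 0 to 211 with each library left out, where the lone pool of a group is assumed to vary like the other group. For translational efficiency the count of 0 became 12 with DESeq2 and 0 to 1 with each library left out.

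With an estimated correlation 0 lists passed in total RNA, RPF, translational efficiency and the WT baseline, and by fry 0 passed in the first 3. In total RNA the 5 lists became 3 at a mean of at least 50 counts and 5 to 10 with each library left out. In RPF the 15 lists became 11 at a mean of at least 50 counts, 11 with the length trend removed and 7 to 15 with each pool left out. For translational efficiency the 4 lists became 2 at a mean of at least 50 counts, 1 with protein-coding genes only and 2 to 11 with each library left out. In the WT baseline the 15 lists became 8 with protein-coding genes only and 14 to 17 with each library left out. The correlation of the assays, 0.324, was 0.439 at a mean of at least 50 counts and 0.191 to 0.363 with each library left out. It was 0.307 without lists of other cell types and 0.093 without these lists and Ig and TCR segments.

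Directions turned in 5 cases, with these adjusted p. They were mitochondrially encoded genes in RPF without Anaef 3B (3.504e-07, within a range of 1.712e-16 to 0.861 over the pools left out), cytosolic ribosomal proteins in RPF with the length trend removed (0.176), cytosolic ribosomal proteins in translational efficiency without total RNA WT 3 (0.00129, within 0.00129 to 0.908 over the libraries left out), mitochondrially encoded genes in translational efficiency without RPF Anaef 4B (1.19e-05, within 1.178e-07 to 0.927 over the libraries left out) and mTORC1 components in the WT baseline by fry (0.0082). Of the values for lists that passed, 344 stayed past the threshold in the same direction, 133 no longer passed and 1 turned. Of those for lists that did not pass, 1075 stayed, 71 passed in the same direction and 4 turned. For named genes that passed, 27 values stayed and 33 did not, and for the others 1844 stayed and 107 passed, with no direction turned past the threshold.

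The plasma cell, B cell and helper T cell lists passed in total RNA and RPF with each library left out, as did regulatory T cell and oxidative phosphorylation lists in RPF and naive markers in translational efficiency. Unmasked RPF columns were not run as an alternative. No paired analysis was possible because the genotype groups share no replicate numbers and the labels do not say which animals went into which RPF pool. Simulated changes of 3 on the log2 scale, in genes drawn independently, were recovered at 28% in the interaction, over 18553 genes. In RPF they were recovered at 98%, over the 9557 genes that pass its filter. How far RPF depth limits the interaction was not tested.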

Other observations

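No test in this part was planned; these values were looked up only after the data were seen, and the genes named here were chosen after their values were seen. Each total RNA library held counts of Xist, the RNA of the inactive X chromosome, from 27742 to 136867, and of the Y-linked genes Ddx3y, from 336 to 951, and Eif2s3y, from 136 to 730. The sex of the animals is not analysed here.

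The predicted gene Gm10800 had 3319 counts in RPF Anaef 3B and 177, 241 and 36 in the other RPF libraries. Gm10717 had 3334 counts in the same library and 180, 214 and 30 in the others. Malat1 and Xist, nuclear RNAs, had 0 counts in all 4 RPF libraries. Nras had 9, 6, 10 and 13 counts in the RPF libraries, at 289 and 306 CPM in WT and Anaef total RNA on the scale of the interaction fit.

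Of 261 Ig segments tested for translational efficiency, 40 were higher and 1 lower in Anaef at an unadjusted p under 0.05. In total RNA 113 of 163 and in RPF 112 of 228 were lower at that level. Whether this reflects masking, shared reads or RNA from different cells was not tested.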
